A study of Mus musculus with 32 samples.

How the data were processed

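Gene expression was measured on 32 Affymetrix arrays in 5 populations of mouse neurons, each from males that lacked Mecp2 (hemizygous null, the genotype that models Rett syndrome) and from wild-type littermates. Per the labels, brain slices were treated with pronase and triturated, fluorescent cells were aspirated by hand, and RNA went through 2 rounds of T7 amplification before biotin labelling. Each array held 27 to 173 cells in the older-age set and 63 to 106 cells in the younger set. All arrays came from 1 mouse except 3 fast-spiking arrays, each of which pooled cells of 2 mice. The labels name 9 amplification batches, and each batch held a single population with both genotypes. Batch and population therefore cannot be told apart, while genotype can be compared within every batch.

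For 26 arrays (fast-spiking, layer 5, older locus coeruleus and Purkinje) the deposited values are log2 probe set summaries from GCRMA, per the submitters' processing notes, which give no version. Their array medians were 3.18 to 3.42 and their values ran from 0.337 to 15.8. For the 6 arrays of younger locus coeruleus the deposited values are on a log2 scale too, but the authors' method was not stated. Their array medians were 5.45 to 5.47 and their values ran from 2.73 to 14.4, so this set was on another scale and had been normalized separately. Levels and fold changes were therefore not compared in size between the 2 sets, and the planned test of the difference between the null effects at the older and the younger age was not run. Detection calls were not used here, depth per array is unknown, and the number of arrays limits the precision. The GCRMA set has a floor that differs between probe sets. The 3764 genes under the filter with an SD under 0.1 over the 26 arrays had means of 1.83 to 3.04 (5th to 95th percentile), but some low probe sets stayed flat at higher values, in 1 marker at 4.53 ± 0.04. A fold with 1 group at the floor depends on the background model.

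The table held 45101 probe sets, of which 34958 had 1 gene symbol, 932 had several and 9211 had none. Of the single-symbol probe sets, 34754 matched a RefSeq gene by Entrez identifier and 204 did not. The RefSeq table was used for names, gene spans and the order of neighbouring genes, and no position is printed because the build behind the array's gene names was not given. For each of 18194 genes, the probe set with the highest mean over the 26 older-age arrays was used, and a span was available for 18032. In each fit, the 9097 genes with a mean at or above the median over all genes were kept. No probe set with 1 gene symbol was named Mecp2, so Mecp2 itself was not analysed and its loss was not checked in these arrays.

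Each population was fitted alone with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend), as null minus wild type. P values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. The average null effect over the 4 older-age populations and the difference of null effects between them (a moderated F test) came from 1 fit of the 26 arrays. A long gene score, the mean log2 value of kept genes that span at least 100 kb minus the mean of the other kept genes, was computed per array and tested by exact two-sided permutation. Markers of the 4 older-age populations were compared in wild type, each population against the mean of the other 3. The 31 gene lists held 1055 entries, of which 925 matched a gene in the table. Lists with at least 5 kept members were tested with limma's camera at a preset correlation of 0.01, and with an estimated correlation and with fry as alternatives. Figures were drawn from the same tables.

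Comparisons, gene lists and the rule for named genes were fixed before the data were examined. The rule took Mecp2 and Irak1 in every comparison, then the 8 largest increases and 8 largest decreases among genes with an adjusted p under 0.05 and no overlap between the arrays of the groups. It also took up to 4 kept members with the smallest p of each list described, and the 8 genes with the smallest adjusted p for the difference between populations. Rab39b in locus coeruleus, Pvalb in layer 5, Olig1 and Zbtb16 in Purkinje cells, and Fundc2, Atp7a, Col4a1 and Col4a2 in the average effect were chosen after their values were seen. The other genes given for the difference between populations are those named elsewhere that also passed its test.

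The fits were tested on simulated data with 9097 genes, of which 100 carried a log2 change of 1 and 100 a log2 change of 2. At a change of 2, recovery was 88% in fast-spiking, 87% in layer 5, 70% in older locus coeruleus, 76% in Purkinje and 98% in younger locus coeruleus settings. At a change of 1, recovery was 40%, 47%, 22%, 46% and 83% in the same order. The average effect recovered 95% and the difference between populations 18% at a change of 1. Unchanged genes made up 2 of 94 to 5 of 91 calls. A shift of 0.15 put on long genes was recovered as 0.160, and without a shift the score difference was 0.00697. When 1 list was shifted, 1 list was called. The simulated noise was independent between genes, so these checks cannot show how correlation between genes affects the scores and lists. For the average effect and the difference between populations, each gene had the same simulated noise in every population. The checks therefore cannot show whether a spread that differs between populations adds calls there. For the difference, the change was put on the older locus coeruleus alone, so its recovery holds for that case only.

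Replicate numbers were checked for pairing by correlating the residuals of null and wild-type arrays. In Purkinje cells each of 3 null arrays correlated best with the wild-type array of its own number (r = 0.180 to 0.254 across genes, which are not independent replicates), and blocking on the number gave 7 genes where the unblocked fit gave 5. The alternatives covered the low-value filter, normalization, the variance model, array weights, the number of cells, the probe set rule, replicate and batch blocks, 1 fit over all 32 arrays, a plain test per gene, pooled mice, gene span and each array left out. One fit over all 32 arrays mixes both value scales.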

Results

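Expression was measured in 10 groups of arrays: 5 neuron populations, each from Mecp2 null males and wild-type littermates. Mecp2 encodes a protein that binds methylated DNA, and the series asks how its loss alters expression in identified neuron types. Fast-spiking parvalbumin interneurons of motor cortex (G42 reporter line) had 4 null and 4 wild-type arrays. Layer 5 thick tufted pyramidal neurons of motor cortex (YFPH line), tyrosine hydroxylase neurons of the locus coeruleus at the older age, Purkinje cells of the cerebellum (G42 line) and locus coeruleus neurons at the younger age had 3 and 3 each. Labelled ages were 37 to 48 days for the fast-spiking set, 38 to 40 days for layer 5, 38 to 41 days for the older locus coeruleus and 22 to 24 days for the younger set; no age was given for Purkinje cells. The series calls the younger age presymptomatic. Mean correlations of an array with the others of its group were 0.982 to 0.995 in the older-age set and 0.988 to 0.996 in the younger set. Levels are given as log2 mean ± SD, changes as log2 null minus wild type ± SE from limma, and adjusted p values come from limma.

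The wild-type arrays carried the markers of the labelled populations. In fast-spiking arrays, the 15 interneuron markers averaged 11.8 ± 0.15 (n = 4), against 4.12 ± 0.16 in layer 5 arrays (n = 3). The layer 5 list averaged 9.96 ± 0.07 in its own arrays, the locus coeruleus list 10.9 ± 0.13 and the Purkinje list 13.4 ± 0.03. Every marker kept in the test was higher in its own population than in the mean of the other 3: 13 of 13 for fast-spiking, 9 of 9 for layer 5, 9 of 9 for locus coeruleus and 11 of 11 for Purkinje cells. In the locus coeruleus test the count was 4 without wild-type replicate 1, 4 without replicate 2 and 5 without replicate 3. The filter was applied anew in these fits, so the number of markers kept could change. Without the filter the count was 13 of 13 in locus coeruleus and 14 of 15 in layer 5. Among all genes, 1847 to 3154 were higher in a given population, so such calls were common. Oligodendrocyte markers varied between layer 5 arrays, at 6.50, 5.67 and 4.16 in wild type and 4.23, 6.87 and 7.41 in null arrays.

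In fast-spiking interneurons, 4 genes were higher and 1 was lower in null arrays (n = 4 and 4). Rab39b (Entrez gene 67790), a small GTPase of vesicle traffic, rose from 9.21 ± 0.26 to 11.59 ± 0.28, which is 5.18-fold (log2 change 2.37 ± 0.19, adjusted p = 0.00173). Col4a1, a collagen chain of basement membranes, rose from 7.51 ± 0.52 to 9.88 ± 0.35, or 5.19-fold (adjusted p = 0.0173), while its second probe set, at a mean of 6.66, had a change of 0.17. Gsg1l, an auxiliary subunit of AMPA receptors, rose 3.79-fold (log2 change 1.92 ± 0.23, adjusted p = 0.0149), and Adgrl2, a latrophilin adhesion receptor, rose 2.67-fold (1.42 ± 0.16, adjusted p = 0.0131). Fgf11, an intracellular member of the fibroblast growth factor family, fell by 2.68 ± 0.30 on the log2 scale, from 8.41 ± 0.39 to 5.74 ± 0.40 (adjusted p = 0.0131). The second Rab39b probe set above background, at a mean of 9.62, had an average change of -0.01 over the 4 older-age populations, so the increase rests on 1 probe set.

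Of 23 gene lists tested in fast-spiking interneurons, 4 passed camera. The neuropeptide and growth factor list was lower, with a median change of -0.48 and a mean of -0.75. Of its 16 kept members none passed over all genes or when adjusted over the list alone, and 3 had an unadjusted p under 0.05 (list adjusted p = 0.000722, and adjusted p = 0.689 with an estimated correlation). Its members Npy, a peptide transmitter, and Igf1, a growth factor, had changes of -1.46 ± 0.49 (adjusted p = 0.860) and -1.29 ± 0.47 (adjusted p = 1). The list of neuronal cell adhesion genes outside the cadherins was higher, with a median change of 0.07, a mean of 0.28 and 29 of 50 members positive. None passed over all genes, 9 had an unadjusted p under 0.05, and 5 were higher when adjusted over the list alone (adjusted p = 5.32e-05, and adjusted p = 0.689 with an estimated correlation). The textbook list of long neuronal genes was also higher, with a median change of 0.16 over 60 members. None passed over all genes, 12 had an unadjusted p under 0.05, and 4 were higher when adjusted over the list alone (adjusted p = 3.46e-07, and adjusted p = 0.689 with an estimated correlation). The axonal adhesion gene Cntn4 (1.17 ± 0.21, adjusted p = 0.156) and the synaptic adhesion gene Lrrtm4 (1.37 ± 0.28, adjusted p = 0.212) belong to this list and to the adhesion list. The netrin-related Ntng1 (1.08 ± 0.22, adjusted p = 0.212) belongs to the adhesion list only. The imprinted gene list was higher, with a median of 0.08 over 22 members, none past over all genes or over the list alone and 2 at an unadjusted p under 0.05 (adjusted p = 0.0102, and adjusted p = 0.689 with an estimated correlation). Plagl1, an imprinted transcription factor gene, had a change of 0.76 ± 0.19 (adjusted p = 0.489). Irak1, a gene next to Mecp2, had a change of -0.03 ± 0.15 (adjusted p = 1).

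The fast-spiking test called 5 of 9097 genes, and 388 had an unadjusted p under 0.05. Named genes had no overlap between the groups, so the sign of a within-batch difference was fixed; within the 3 amplification batches the differences of the 5 genes were 0.668 to 1.35 times those of the whole set. The count was 1 without wild-type replicate 1 or 2, 2 without null replicate 1, 10 without null replicate 2 and 1 without null replicate 3 or 4. It was 0 without the 3 pooled arrays (189 at an unadjusted p under 0.05), 21 with amplification batch as a block (all 5 calls kept), 72 in 1 fit over all 32 arrays and 1 to 15 under the other settings. The mean of all probe sets of a gene gave 1 higher and 4 lower and kept 2 of the 5 calls, so the excess of higher genes depends on the probe set rule.

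In layer 5 pyramidal neurons, 16 genes were higher and 11 lower in null arrays (n = 3 and 3). Chn2 (Entrez gene 69993), a Rac GTPase-activating protein, was 2.69 ± 0.51 in wild type, at the floor, and 6.94 ± 0.42 in null arrays (4.25 ± 0.34, adjusted p = 0.01). Cbln2, a secreted organizer of synapses, rose 9.12-fold (3.19 ± 0.31, adjusted p = 0.01), and Rab39b rose 7.83-fold (2.97 ± 0.38, adjusted p = 0.0284). Hpca, the calcium sensor hippocalcin, rose from 9.35 ± 0.42 to 11.28 ± 0.19 (adjusted p = 0.0173). Chst11, an enzyme of chondroitin sulfate, rose by 2.47 ± 0.37 (adjusted p = 0.0466), Bmper, a secreted regulator of bone morphogenetic proteins, by 2.34 ± 0.35 (adjusted p = 0.0466) and Pdzrn3, a ubiquitin ligase, by 2.22 ± 0.30 (adjusted p = 0.0335). The uncharacterised gene 2900055J20Rik rose by 2.43 ± 0.32 (adjusted p = 0.0335).

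Among the genes lower in layer 5, Doc2b, a calcium sensor of transmitter release, fell from 8.22 ± 0.37 to 5.14 ± 0.48, or 8.50-fold (adjusted p = 0.01). Slc29a4, a monoamine transporter, fell from 8.13 ± 0.03 to 4.71 ± 0.70 (adjusted p = 0.01), and Arhgdib, an inhibitor of Rho GTPase cycling, fell by 3.58 ± 0.47 (adjusted p = 0.0322). Fxyd7, a regulator of the sodium pump, fell from 9.23 ± 0.07 to 7.47 ± 0.15 (adjusted p = 0.01). Trim36, a ubiquitin ligase, fell by 2.10 ± 0.22 (adjusted p = 0.01), Fam20a fell by 2.30 ± 0.29 (adjusted p = 0.0284), the growth factor gene Pdgfb fell by 2.02 ± 0.25 (adjusted p = 0.0250) and Mrap2, a melanocortin receptor accessory protein, fell by 1.79 ± 0.24 (adjusted p = 0.0335). The null means of Arhgdib and Fam20a, 3.25 and 3.77, may lie near the floor, so the size of these falls may depend on the background model. Irak1 had a change of 0.04 ± 0.24 (adjusted p = 0.977), which turned to -0.03 after quantile normalization and -0.06 after median centring.

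Of 24 lists tested in layer 5, 4 passed camera, each lower in null arrays. The synaptic vesicle and exocytosis list had a median change of -0.08. Of its 38 members, Doc2b was lower over all genes, and 4 were higher and 3 lower when adjusted over the list alone (adjusted p = 0.00318, and adjusted p = 0.444 with an estimated correlation). The active zone gene Rims3 had a change of 2.08 ± 0.34 (adjusted p = 0.0626) and the vesicle protein gene Syt4 one of -0.76 ± 0.13 (adjusted p = 0.0650), so members went both ways. The cholesterol synthesis and uptake list had a median of -0.20 over 20 members, with none past over all genes, 3 at an unadjusted p under 0.05 and 3 lower when adjusted over the list alone (adjusted p = 0.00318, and adjusted p = 0.444 with an estimated correlation). Hmgcs1, an early enzyme of the pathway, had a change of -0.27 ± 0.06 (adjusted p = 0.169) and the later enzyme gene Nsdhl one of -0.65 ± 0.17 (adjusted p = 0.213). The list of GABA and glycine receptors and the inhibitory synapse had a median of -0.10 over 16 members, with none past over all genes, 5 at an unadjusted p under 0.05 and 1 lower when adjusted over the list alone (adjusted p = 0.0486, and adjusted p = 0.490 with an estimated correlation). Gabra5, a GABA receptor subunit, had a change of -0.52 ± 0.11 (adjusted p = 0.119). The adhesion list outside the cadherins had a median of -0.07 over 50 members, with none past over all genes, 14 at an unadjusted p under 0.05 and 1 lower when adjusted over the list alone (adjusted p = 0.0389, and adjusted p = 0.444 with an estimated correlation). The contactin gene Cntn6 had a change of -1.18 ± 0.20 (adjusted p = 0.0641). Oligodendrocyte markers averaged 5.44 ± 1.19 in wild-type and 6.17 ± 1.70 in null layer 5 arrays. The parvalbumin gene Pvalb, a marker of fast-spiking cells, was 7.62 ± 1.64 in wild-type and 10.62 ± 1.25 in null layer 5 arrays (adjusted p = 0.244). The other 14 markers of that list averaged 3.87 ± 0.12 and 3.96 ± 0.23.

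The layer 5 test called 27 of 9097 genes, and 980 had an unadjusted p under 0.05. Within the 2 amplification batches, where the signs were again fixed by the absence of overlap, the differences of the 16 named genes were 0.561 to 1.38 times those of the whole set. With batch as a block the count was 14, and 13 of the 27 calls were kept. The count was 2 without wild-type replicate 1 or 2, 12 without null replicate 1 or 2, and 0 without null replicate 3, where 732 genes had an unadjusted p under 0.05. Over the other settings it ran from 0 in a plain test per gene (845 at an unadjusted p under 0.05) to 108 in 1 fit over all 32 arrays. The split of 16 higher and 11 lower turned to 3 and 7 without a variance trend, 7 and 8 with the mean of all probe sets, and 15 and 17 with the number of cells as a covariate.

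In locus coeruleus neurons at the older age, 39 genes were higher and 23 lower in null arrays (n = 3 and 3). Slc12a7 (Entrez gene 20499), a potassium chloride cotransporter, was 3.45 ± 0.42 in wild type, near the floor, and 9.17 ± 0.24 in null arrays (5.71 ± 0.28, adjusted p = 0.00126). Ptprg, a receptor tyrosine phosphatase, rose from 7.38 ± 0.32 to 10.03 ± 0.11, or 6.26-fold (adjusted p = 0.0123), and Col4a1 rose from 8.57 ± 0.39 to 11.08 ± 0.26 (adjusted p = 0.0157; 0.91 at its second probe set). Adgrl2 rose from 4.53 ± 0.77 to 8.36 ± 0.46 (adjusted p = 0.0184), with a change of 1.70 at its second probe set above background. Other probe sets of Ptprg had 3.59 and 3.53. The guidance receptor genes Ephb1 and Nrp2 each rose by 2.68 (SE 0.24 and 0.39, adjusted p = 0.0152 and 0.0398). Gab1, an adaptor of receptor tyrosine kinases, rose by 2.67 ± 0.30 (adjusted p = 0.0184), and the adaptor gene Stac by 2.77 ± 0.42 (adjusted p = 0.0441). The wild-type mean of Stac, 3.95, may lie near the floor. Rab39b, chosen after its values were seen, rose 3.55-fold (1.83 ± 0.18, adjusted p = 0.0152).

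Among the genes lower in the older locus coeruleus, Adcyap1, which encodes the neuropeptide PACAP, fell from 8.45 ± 0.20 to 4.28 ± 1.28, or 18.0-fold (adjusted p = 0.0373). Plin5, a lipid droplet protein, fell from 9.28 ± 0.45 to 4.97 ± 0.94, or 19.8-fold (adjusted p = 0.0184), and Ptger4, a prostaglandin receptor, fell by 3.95 ± 0.33 (adjusted p = 0.0123). The serotonin receptor gene Htr2c fell by 3.21 ± 0.46 (adjusted p = 0.0398), Fxyd7 fell by 3.66 ± 0.53 (adjusted p = 0.0398) and Vstm2a fell by 3.75 ± 0.43 (adjusted p = 0.0184). Lats2, a kinase of the Hippo pathway, fell by 2.83 ± 0.27 (adjusted p = 0.0152), and Arhgef15, a Rho exchange factor, fell by 2.72 ± 0.22 (adjusted p = 0.0123). The null means of Htr2c, Fxyd7, Lats2 and Ptger4 were 3.81, 4.05, 4.08 and 4.11. These and the null mean of Adcyap1 may lie near the floor of their probe sets, so the folds may depend on the background model. Irak1 had a change of -0.24 ± 0.19 (adjusted p = 0.690).

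Of 26 lists tested in the older locus coeruleus, 2 passed camera, both higher. The textbook list of long neuronal genes had a median change of 0.27 over 59 members. None passed over all genes, 18 had an unadjusted p under 0.05, and 10 were higher and 1 lower when adjusted over the list alone (adjusted p = 0.000513, and adjusted p = 0.482 with an estimated correlation). Members included the netrin receptor gene Unc5c (1.60 ± 0.26, adjusted p = 0.0549), the protocadherin gene Pcdh9 (1.11 ± 0.20, adjusted p = 0.0750) and the adhesion gene Ntm (1.38 ± 0.25, adjusted p = 0.0787). The list of cytosolic ribosomal proteins had a median of 0.18 over 40 members, with none past over all genes or over the list alone and 12 at an unadjusted p under 0.05 (adjusted p = 3.73e-07, and adjusted p = 0.482 with an estimated correlation). Rpl27a had a change of 0.91 ± 0.22 (adjusted p = 0.154) and Rpl14 one of 0.74 ± 0.18 (adjusted p = 0.155).

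The older locus coeruleus test called 62 of 9097 genes, and 1078 had an unadjusted p under 0.05; all 6 arrays came from 1 batch. The count was 1 without wild-type replicate 1 or 2, 15 without wild-type replicate 3, 207 without null replicate 1, 2 without null replicate 2 and 1 without null replicate 3. With the number of cells as a covariate it was 1, without the filter 40, with array weights 957, in 1 fit over all 32 arrays 368 and in a plain test per gene 0 (965 at an unadjusted p under 0.05). The split of 39 higher and 23 lower turned to 32 and 33 with the mean of all probe sets, 20 and 20 without the filter, and 11 and 11 with replicate number as a block.

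In Purkinje cells, 2 genes were higher and 3 lower in null arrays (n = 3 and 3). Pcdh11x (Entrez gene 245578), an X-linked protocadherin, rose from 4.61 ± 0.61 to 8.55 ± 0.27, or 15.4-fold (adjusted p = 0.00624), and Map3k20, a stress-activated kinase, rose from 4.49 ± 0.02 to 7.38 ± 0.32 (adjusted p = 0.00624). The gene E130218I03Rik fell from 8.46 ± 0.61 to 2.23 ± 0.03, which is the floor (-6.23 ± 0.33, adjusted p = 0.000606). Mdfi, an inhibitor of myogenic transcription factors, fell from 7.42 ± 0.86 to 3.14 ± 0.31 (adjusted p = 0.0167), and Cldn34c1, of the claudin family, from 7.76 ± 0.58 to 3.64 ± 0.08 (adjusted p = 0.00577). The lower groups of Pcdh11x, Map3k20, Mdfi and Cldn34c1 may lie at or near the floor of their probe sets, so these folds may depend on the background model. Irak1 had a change of -0.09 ± 0.41 (adjusted p = 1.00).

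Of 26 lists tested in Purkinje cells, 2 passed camera, both higher. The textbook list of long neuronal genes had a median of 0.17 over 48 members, with none past over all genes, 8 at an unadjusted p under 0.05 and 1 higher when adjusted over the list alone (adjusted p = 0.00286, and adjusted p = 0.919 with an estimated correlation). Its members Cntn4 and Pde10a, a phosphodiesterase gene, had changes of 1.07 ± 0.21 (adjusted p = 0.272) and 0.65 ± 0.16 (adjusted p = 0.495). The imprinted gene list had a median of 0.25 over 21 members, with none past over all genes, 4 at an unadjusted p under 0.05 and 1 higher when adjusted over the list alone (adjusted p = 0.000983, and adjusted p = 0.278 with an estimated correlation). Its members Nap1l5, Plagl1 and Sgce had changes of 0.45 ± 0.09 (adjusted p = 0.278), 0.66 ± 0.17 (adjusted p = 0.519) and 1.2 ± 0.36 (adjusted p = 0.680). Oligodendrocyte markers averaged 4.56 ± 0.14 in wild-type and 4.25 ± 0.18 in null arrays (n = 3 each). This rested on Olig1, chosen after its values were seen, at 8.29 ± 0.20 and 4.00 ± 1.79 (adjusted p = 0.218); without it the list averaged 4.28 ± 0.14 and 4.27 ± 0.09. The Purkinje test called 5 of 9097 genes, and 483 had an unadjusted p under 0.05. Within the 2 batches, with signs fixed as above, the differences of the 5 genes were 0.899 to 1.2 times those of the whole set, and with batch as a block all 5 calls were kept. The count was 1 without wild-type replicate 1, 3 without wild-type replicate 2, 2 without null replicate 2 and 1 without null replicate 3. It was 0 in a plain test per gene (439 at an unadjusted p under 0.05) and 79 in 1 fit over all 32 arrays.

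Averaged over the 4 older-age populations (13 null and 13 wild-type arrays), 146 genes were higher and 43 lower in null neurons. Rab39b had the largest average increase named by the rule, 4.68-fold (2.23 ± 0.15, adjusted p = 8.11e-10). Its changes were 2.37, 2.97, 1.83 and 1.74 in fast-spiking, layer 5, locus coeruleus and Purkinje arrays, and in Purkinje cells alone it did not pass (adjusted p = 0.136). Focad, a focal adhesion gene, rose by 0.55 ± 0.09 (adjusted p = 0.000844). Chosen after their values were seen, the collagen genes Col4a1 and Col4a2 rose by 1.99 ± 0.26 (adjusted p = 3.99e-05) and 1.79 ± 0.16 (adjusted p = 3.44e-07), with changes in layer 5 of 0.45 and 0.05. Atp7a, a copper transporter, fell by 1.75 ± 0.25 (adjusted p = 0.000162), and Fundc2, a mitochondrial outer membrane protein, rose by 0.73 ± 0.08 (adjusted p = 5.73e-06). Irak1 had a change of -0.08 ± 0.14 (adjusted p = 0.899).

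**Figure D1:**
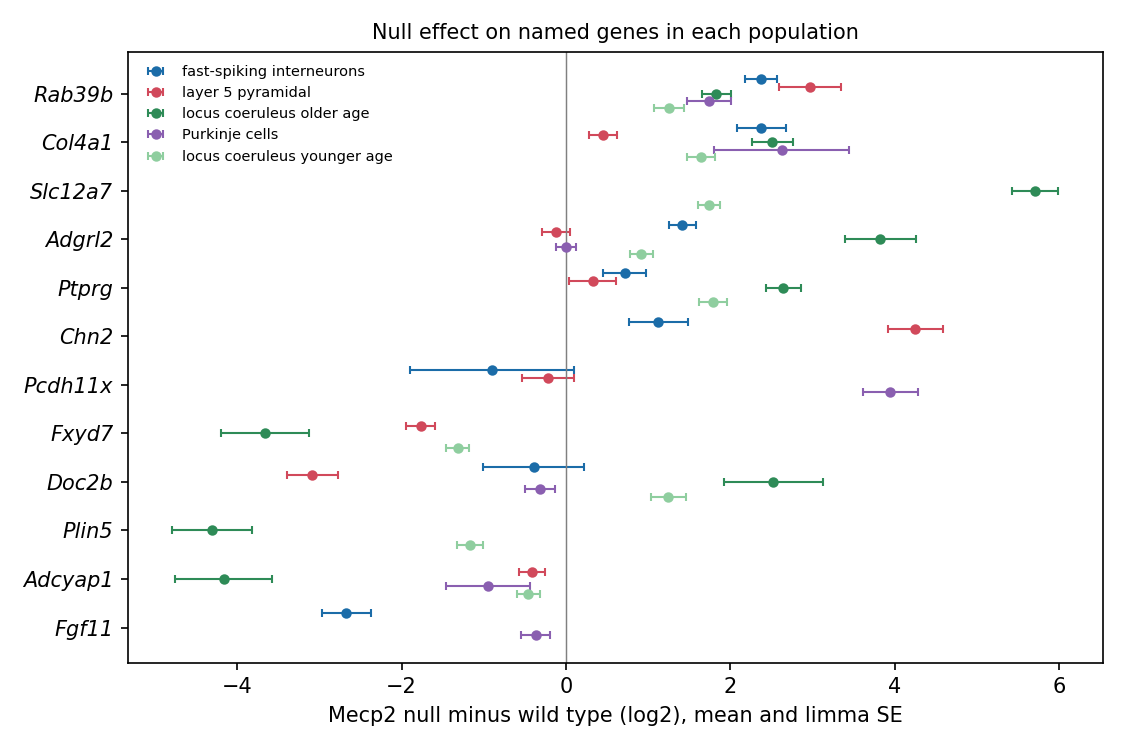
Log2 change (null minus wild type, x axis) of named genes (y axis) in each population. Bars are limma SE, and a gene is absent where it lay below the filter in that population. Rab39b lies between 1.25 and 2.97 in all 5 populations, and the younger locus coeruleus is on another value scale than the older-age sets.

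Of 26 lists tested on the average effect, 8 passed camera. In the textbook list of long neuronal genes, 10 of 63 members rose and none fell over all genes, and 15 were higher and 1 lower when adjusted over the list alone (median 0.20, adjusted p = 4.85e-08, and adjusted p = 0.0549 with an estimated correlation). These included Cntn4 (0.91 ± 0.13, adjusted p = 0.000130), Pcdh9 (0.56 ± 0.09, adjusted p = 0.000714), Unc5c (0.59 ± 0.13, adjusted p = 0.00996) and the neurexin-family gene Cntnap2 (0.34 ± 0.07, adjusted p = 0.0129). In the adhesion list outside the cadherins, 9 of 49 members rose and 1 fell, and 11 were higher and 6 lower when adjusted over the list alone (median 0.11, adjusted p = 0.0172, and adjusted p = 0.383 with an estimated correlation). The teneurin Tenm3 rose by 0.81 ± 0.12 (adjusted p = 0.000143), Dscam by 0.84 ± 0.17 (adjusted p = 0.00638) and Flrt3 by 1.16 ± 0.25 (adjusted p = 0.00934). In the neuropeptide and growth factor list, 1 of 14 members fell, over all genes and over the list alone (median -0.16, adjusted p = 0.0126, and adjusted p = 0.0549 with an estimated correlation). That member was Adcyap1 (-1.38 ± 0.22, adjusted p = 0.000450), while Igf1 and Tac1, a tachykinin gene, had changes of -0.65 ± 0.25 (adjusted p = 0.232) and -0.64 ± 0.27 (adjusted p = 0.311). In the imprinted list, 1 of 22 members rose, with 2 higher over the list alone (median 0.09, adjusted p = 0.0395, and adjusted p = 0.383 with an estimated correlation). Plagl1 rose by 0.68 ± 0.11 (adjusted p = 0.000401), and Ppp1r9a, a neuronal actin-binding protein gene, had a change of 0.35 ± 0.09 (adjusted p = 0.0536).

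The other 4 lists that passed on the average effect had no member past over all genes. The list of GABA and glycine receptors and the inhibitory synapse was lower (median -0.16 over 18 members, 2 at an unadjusted p under 0.05 and none over the list alone, adjusted p = 0.0172, and adjusted p = 0.383 with an estimated correlation). Nlgn2, an adhesion protein of inhibitory synapses, had a change of -0.29 ± 0.09 (adjusted p = 0.146) and the chloride transporter Slc12a5 one of -0.19 ± 0.08 (adjusted p = 0.337). The synaptic vesicle list was lower (median -0.09 over 39 members, 10 at an unadjusted p under 0.05, adjusted p = 0.0346, and adjusted p = 0.383 with an estimated correlation). When adjusted over the list alone, 3 of its members were higher and 4 lower. Unc13b, a priming factor of vesicles, had a change of -0.83 ± 0.24 (adjusted p = 0.0699), synaptophysin (Syp) one of -0.59 ± 0.19 (adjusted p = 0.115), Rims3 one of 0.75 ± 0.22 (adjusted p = 0.0914) and Syt12 one of 0.86 ± 0.28 (adjusted p = 0.129). The cholesterol list was lower (median -0.10 over 21 members, 3 at an unadjusted p under 0.05 and none over the list alone, adjusted p = 0.0172, and adjusted p = 0.383 with an estimated correlation). Its members Nsdhl and Ebp had changes of -0.28 ± 0.11 (adjusted p = 0.245) and -0.34 ± 0.15 (adjusted p = 0.325). The ribosomal list was higher (median 0.08 over 41 members, 2 at an unadjusted p under 0.05 and none over the list alone, adjusted p = 0.0172, and adjusted p = 0.607 with an estimated correlation), with Rpl7 at 0.18 ± 0.08 (adjusted p = 0.340).

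The average test called 189 of 9097 genes, and 1091 had an unadjusted p under 0.05. Of these 189, 127 had the same sign in all 4 populations, 53 in 3 and 9 in 2. Median centring split 186 genes into 121 higher and 65 lower, batch as a block gave 286 genes and array weights gave 736.

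Null effects differed between the 4 older-age populations for 106 of 9097 genes by the F test, and 681 genes had an unadjusted p under 0.05. The largest effect lay in the locus coeruleus for 63 of them, in layer 5 for 26, in fast-spiking interneurons for 10 and in Purkinje cells for 7. Adgrl2 had changes of 1.42, -0.12, 3.83 and -0.00 in fast-spiking, layer 5, locus coeruleus and Purkinje arrays (adjusted p = 2.63e-06). In the same order, Chn2 had 1.13, 4.25, 0.03 and 0.16 (adjusted p = 7.03e-05), and Vstm2a -0.18, -0.38, -3.75 and -0.22 (adjusted p = 1.2e-05). Nwd2 had its largest change in fast-spiking interneurons, -2.97 (adjusted p = 7.37e-05). Stac at 2.77, Kcnmb2, a subunit of calcium-activated potassium channels, at 2.44 and Car8, an inhibitor of the inositol trisphosphate receptor, at 2.12 had theirs in the locus coeruleus (adjusted p = 7.37e-05, 7.37e-05 and 0.000199). The GCRMA floor limits this comparison, since a gene at the floor cannot fall, though it can rise. The test also uses 1 spread per gene over the 26 arrays. That spread may be too small for a gene that varies in 1 population and lies flat in others. The count of 106 may therefore be too high. Car8 was at the floor in both genotypes in fast-spiking (3.06 and 3.07) and layer 5 arrays (3.11 and 3.17), and near the top in Purkinje arrays (14.8 in both). Stac was at the floor in fast-spiking and layer 5, Kcnmb2 in layer 5 and Purkinje, and Chn2 in locus coeruleus and Purkinje arrays. Of the 106 genes, 60 reached 5 in at least 1 genotype in every population, while 21 were under 5 in both genotypes in 1 population, 23 in 2 and 2 in 3. Macrod1, an ADP-ribose hydrolase, had opposite signs, with 1.65 in layer 5 and -2.67 in locus coeruleus (adjusted p = 7.92e-05), as did Doc2b with -3.09 and 2.52 (adjusted p = 0.00278). The F test does not test the sign in a single population. Both rises began at low levels, from 3.815 to 5.465 for Macrod1 in layer 5 and from 3.882 to 6.405 for Doc2b in locus coeruleus. The rise of Doc2b was not called in the locus coeruleus alone. Irak1 gave no call (adjusted p = 1). Without layer 5 null replicate 3 the count was 67, without the filter 220 and with array weights 480.

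Relative to other genes, long genes were higher in null neurons over the 4 older-age populations combined. The long gene score addresses whether the null effect depends on gene length. In fast-spiking arrays the score was 0.165 ± 0.051 in wild type and 0.298 ± 0.034 in null arrays, a difference of 0.133 (exact permutation p = 0.0286, adjusted p = 0.125). The differences were 0.177 in the older locus coeruleus, 0.0975 in Purkinje cells and, on its own value scale, 0.127 in the younger locus coeruleus (exact p = 0.1 each, the smallest that 3 against 3 allows, adjusted p = 0.125). With the mean of all probe sets it was 0.0806 in fast-spiking (exact p = 0.0571) and 0.0529 in Purkinje arrays (exact p = 0.3), and the median in place of the mean gave 0.108 in fast-spiking (exact p = 0.114). In layer 5 it was 0.0231 (exact p = 0.6), and 1 of 3 null arrays lay above the highest wild-type array, against all null arrays in the other populations. Combined over the 4 older-age populations, the difference was 0.108 (exact permutation p = 7.14e-05, two-sided). Within batches it was 0.127, 0.149 and 0.132 in fast-spiking, 0.0241 and 0.0211 in layer 5, and 0.0913 and 0.110 in Purkinje arrays. A test of whether the differences vary between populations, chosen after seeing the data, did not pass (F = 3.27, permutation p = 0.0537).

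Genes that rose on average were long: 88 of 144 with a span (61.1%) spanned at least 100 kb, against 5 of 43 genes that fell (11.6%) and 15.3% of genes that did not pass. Their median span was 130 kb, against 21.5 kb for those that fell and 26.1 kb for the rest. In layer 5, where the score hardly differed, 8 of 16 genes called higher and 2 of 11 called lower were long, against 15.6% of tested genes. In the older locus coeruleus these were 27 of 39 and 4 of 23, against 15.5%. Among genes of 300 kb or more, the mean change relative to all genes was 0.28 ± 0.03 in the older locus coeruleus, 0.16 ± 0.02 in fast-spiking, 0.13 ± 0.04 in Purkinje and 0.01 ± 0.03 in layer 5 arrays. In the younger locus coeruleus, on another value scale and not compared in size, it was 0.18 ± 0.05.

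**Figure D2:**
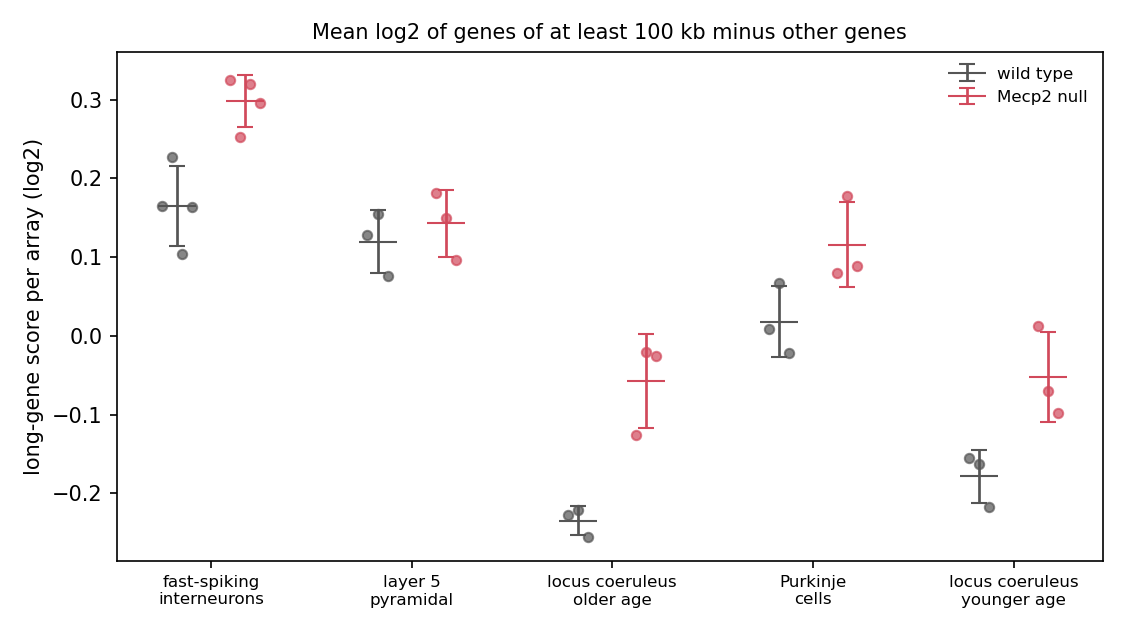
Long gene score of each array (log2, y axis), by population and genotype, with group mean ± SD. All null arrays lie above the highest wild-type array in each population except layer 5, where 1 of 3 does.

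**Figure D3:**
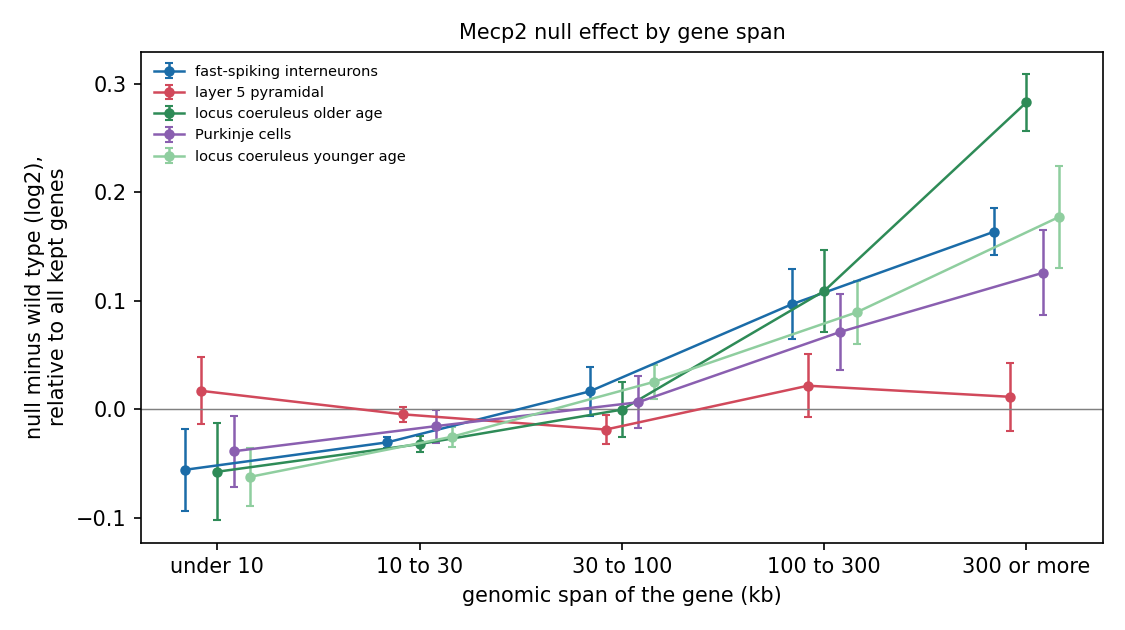
Mean log2 change (null minus wild type) of genes in each span class relative to all kept genes, by population, with SE over arrays. At 300 kb or more the mean runs from 0.01 in layer 5 to 0.28 in the older locus coeruleus; the younger set is on another value scale.

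In locus coeruleus neurons at the younger age, 71 genes were higher and 30 lower in null arrays (n = 3 and 3), on a value scale of their own. Ptprg rose by 1.79 ± 0.17 (adjusted p = 0.00665), Slc12a7 from 6.67 ± 0.15 to 8.41 ± 0.15 (adjusted p = 0.00484) and Col4a1 by 1.64 ± 0.17 (adjusted p = 0.00846; 0.67 at its second probe set). Lypd6, a modulator of nicotinic receptors, rose by 1.59 ± 0.18 (adjusted p = 0.00875), the guidance gene Slit1 by 1.43 ± 0.20 (adjusted p = 0.0176) and the exchange factor gene Spata13 by 1.42 ± 0.16 (adjusted p = 0.00875). Abtb2 rose by 1.60 ± 0.22 (adjusted p = 0.0172), Usp2, a ubiquitin protease, by 1.45 ± 0.28 (adjusted p = 0.0474) and Rab39b, chosen after its values were seen, by 1.25 ± 0.19 (adjusted p = 0.0202). Doc2a, a calcium sensor of transmitter release, fell from 8.92 ± 0.17 to 7.29 ± 0.20 (adjusted p = 0.00660), Fxyd7 fell by 1.32 ± 0.14 (adjusted p = 0.00839) and the chromatin remodeller gene Chd3 fell by 1.22 ± 0.16 (adjusted p = 0.0164). Plin5 fell by 1.17 ± 0.16 (adjusted p = 0.0172), Macrod1 fell by 1.07 ± 0.15 (adjusted p = 0.0185) and Nudt17 fell by 1.10 ± 0.15 (adjusted p = 0.0176). Tm4sf5 and 4930550L24Rik each fell by 0.96 ± 0.16 (adjusted p = 0.0288 and 0.0292). Irak1 had a change of -0.65 ± 0.35 (adjusted p = 0.570).

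Of 25 lists tested at the younger age, 5 passed camera. In the adhesion list outside the cadherins, 3 of 42 members rose over all genes and 7 over the list alone (median 0.13, adjusted p = 0.00525, and adjusted p = 0.926 with an estimated correlation). Tenm3 rose by 1.01 ± 0.12 (adjusted p = 0.00875), Flrt1 by 0.83 ± 0.13 (adjusted p = 0.0229) and Opcml by 1.09 ± 0.19 (adjusted p = 0.0369). In the textbook list of long neuronal genes, 3 of 51 members rose over all genes, with 4 higher and 1 lower over the list alone (median 0.14, adjusted p = 0.00161, and adjusted p = 0.926 with an estimated correlation). Pcdh9 rose by 0.55 ± 0.10 (adjusted p = 0.0421) and Dab1, an adaptor of reelin signalling, by 0.76 ± 0.13 (adjusted p = 0.0298). In the list of GABA and glycine receptors and the inhibitory synapse, 1 of 13 members fell over all genes and 3 over the list alone (median -0.14, adjusted p = 0.0136, and adjusted p = 0.926 with an estimated correlation). The GABA receptor subunit Gabrg1 fell by 0.85 ± 0.13 (adjusted p = 0.0229), and the glycine receptor subunit Glra2 had a change of -0.58 ± 0.15 (adjusted p = 0.132). The list of X-linked neighbours of Mecp2 was lower (median -0.08 over 19 members, none past over all genes, 4 at an unadjusted p under 0.05 and 1 lower over the list alone, adjusted p = 0.0321, and adjusted p = 0.561 with an estimated correlation), with Srpk3 at -0.89 ± 0.21 (adjusted p = 0.102). The ribosomal list was higher (median 0.12 over 42 members, none past over all genes or over the list alone, 8 at an unadjusted p under 0.05, adjusted p = 0.00161, and adjusted p = 0.561 with an estimated correlation), with Rpsa at 0.28 ± 0.07 (adjusted p = 0.106). Oligodendrocyte markers averaged 5.00 ± 0.01 in wild-type and 5.13 ± 0.03 in null arrays, astrocyte markers 6.06 ± 0.07 and 6.19 ± 0.08, and microglia markers 5.12 ± 0.02 and 4.97 ± 0.16 (n = 3 each).

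The younger locus coeruleus test called 101 of 9097 genes, and 1044 had an unadjusted p under 0.05; all 6 arrays came from 1 batch. The count was 0 without wild-type replicate 1 (785 at an unadjusted p under 0.05), 4 without wild-type replicate 2, 9 without wild-type replicate 3, 283 without null replicate 1 and 23 without null replicate 2. With the number of cells as a covariate it was 27, with the mean of all probe sets of a gene 47, in 1 fit over all 32 arrays 30, in a plain test per gene 5 and with array weights 1292. The split of 71 higher and 30 lower turned to 24 and 23 with the mean of all probe sets, which kept 33 of 86 calls, and to 673 and 619 with array weights.

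The same genes were called at both ages of the locus coeruleus more often than independent calls would give. Of 8242 genes tested at both ages, 20 rose and 9 fell at both, where independence would give 0.301 and 0.0544 (Fisher's exact p = 9.18e-34 and 1.62e-19; genes are not independent replicates). The 29 genes included Slc12a7, Ptprg, Col4a1, Ephb1, Gab1, Tenm3 and Rab39b among those higher, and Plin5, Fxyd7, Doc2a, Macrod1 and Arhgef15 among those lower. All 52 genes called at the older age and kept at the younger had the same sign there, and their mean change in that direction was 0.86 (exact p = 0.1, the smallest possible, adjusted p = 0.124). Of the 154 genes of the average effect kept at the younger age, 150 had the same sign. Because the sets are on different scales, the sizes were not compared and the difference between ages was not tested.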

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

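The tests of the whole X chromosome, of the number of cells, of probe sets without a gene name and of splits balanced within batches were chosen only after the results were seen. Null effects differed between the 4 older-age populations for 106 genes. By the same test, the smallest adjusted p values were 2.63e-06 for Adgrl2, 1.2e-05 for Vstm2a, 7.03e-05 for Chn2, 7.37e-05 each for Nwd2, Kcnmb2 and Stac, 7.92e-05 for Macrod1 and 0.000199 for Car8. Of these, Chn2, Kcnmb2, Stac and Car8 lay at the floor in both genotypes in 2 populations, where a fall could not show but a rise could. Their flat values there also lower the spread that the test uses. Other genes named for a single population also differed: Adcyap1 (0.00105), Chst11 (0.00167), Fgf11 (0.00167), Gab1 (0.0026), Doc2b (0.00278), Map3k20 (0.00336), Lats2 (0.00417), Lypd6 (0.00507) and 2900055J20Rik (0.00522). The same held for Doc2a (0.00697), Ptger4 (0.00787), Ephb1 (0.0153), Usp2 (0.0165), Slc29a4 (0.0175), Fxyd7 (0.0421), Chd3 (0.0426) and Trim36 (0.0448). In 7 probe sets without a single gene name, the average effect passed the threshold, 3 higher and 4 lower in null arrays, of 5072 tested (231 at an unadjusted p under 0.05). In the 4-array fast-spiking groups, none of 26 series of values held an array beyond Dixon's critical value for 4 samples, which chance exceeds in about 1 of 20.

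Splits of the same arrays into groups of the same sizes were fitted in the same way. In fast-spiking interneurons the real split gave 5 genes and the highest of the other splits 1, and 1 of 35 splits gave as many. Most of these splits are unequal within amplification batches, unlike the real one; the 12 equal ones, where the highest other gave 0, are too few for a share under 0.05. The average effect gave 189 genes against at most 26 in other splits, and 1 of 100 drawn splits gave as many. In 100 splits drawn equal within batches the highest other was 45, and again only the real one gave as many. Such a count was thus rare when labels were redrawn. The 10 splits of 3 against 3 arrays are too few for a share under 0.05. There the real counts and the highest others were 27 and 1 in layer 5, 62 and 0 in the older locus coeruleus, 5 and 0 in Purkinje cells, and 101 and 1 in the younger locus coeruleus. For the difference between populations, 2 of 100 splits gave as many genes, the real one with 106 included. Drawn equal within batches, 2 of 100 did so too, the other with 107. Redrawn labels also remove any null effect that the populations share. These splits therefore cannot decide whether the effects differ between populations. The first draw's other split gave 192; it kept the real labels of the locus coeruleus and set fast-spiking batches 3 and 4 against batch 2. The share of the batches in it was not separated from that of the locus coeruleus labels. With batch as a block the count was 144, and 100 of the 106 genes remained.

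Long genes were higher than other genes in null arrays by 0.108 over the 4 older-age populations. Matching the other genes on mean level left 0.104 (exact permutation p = 0.000107), and quantile normalization left 0.108 (0.1075, exact permutation p = 5.71e-05), which argues against level or array distribution as the cause. With the 3-prime minus 5-prime control difference as a covariate, the null coefficient was 0.108 (0.1083, against 0.110 without it, permutation p = 4e-05), which argues against RNA integrity as this control measures it. GC content and the position of probes in a transcript were not tested and stay open. A dependence of the null effect on gene length, a question fixed in advance, may be biological, and it remains a hypothesis while these are untested.

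Rab39b and Fundc2, both raised on average, lie 36 and 31 genes from Mecp2 on the X chromosome, so that DNA carried with the null allele could be a source of their change. The rise of Rab39b rests on 1 probe set, since its second, at a mean of 9.62, had an average change of -0.01. Among X-linked genes within 100 neighbours of Mecp2 on either side, 2 of 66 passed, against 9 of 249 other X-linked genes (odds ratio 0.834, 95% interval 0.0856 to 4.17, Fisher's exact p = 1). The interval is too wide to decide, and a segment limited to these genes stays open. X-linked genes passed in 11 of 315 cases and autosomal genes in 176 of 8752 (odds ratio 1.76, 95% interval 0.855 to 3.28, Fisher's exact p = 0.1), which also leaves the question open. An effect of Mecp2 loss on Rab39b, the biological alternative, was not tested apart from the segment.

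In the locus coeruleus, null replicate 1 stood apart from its group at both ages, with a root mean square deviation of 0.537 against 0.223 to 0.357 in the other older arrays and 0.257 against 0.107 to 0.192 in the younger. Glial and endothelial markers averaged 4.02 in this array against 4.01 to 4.10 in the others at the older age, and 5.34 against 5.42 to 5.47 at the younger, which argues against RNA of those cells. It held 74 cells against 67 to 173, and 80 against 63 to 106, so at each age another array held fewer. At the younger age null replicate 3 held 72 cells, which argues against a low number of cells there. At the older age the other null arrays held 124 and 95 cells, so a part of the number of cells stays open. Its 3-prime minus 5-prime control difference was 4.31 at the older age, above the others at 2.91 to 3.92, but 3.24 at the younger, inside 2.96 to 3.44, so RNA integrity may account for the older array and stays open. Differences between animals were not tested; without this array the counts were 207 and 283.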

How the results depend on the processing

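The following were chosen only after the data were seen: the mean of all probe sets and batch as a block for the long gene score, the test of its difference between populations, and the replicate block and arrays left out for gene lists. Every gene called in a population or on average kept its sign wherever it was tested again, but called genes of single populations had no overlap between the groups, so leaving out an array could not turn theirs. Named genes other than Irak1 kept their side of the threshold in 125 of 143 refits in fast-spiking, 221 of 276 in layer 5, 195 of 240 in older locus coeruleus, 127 of 131 in Purkinje, 231 of 283 in younger locus coeruleus, 275 of 297 in the average and 88 of 88 in the difference between populations. With each array left out they kept it in 66 of 86, 65 of 130, 58 of 132, 51 of 66, 77 of 156, 692 of 702 and 195 of 195 fits in the same order, so calls in single populations often depended on 1 array. These counts include named list members that were not called and that kept their side by staying uncalled. Of the 5 fast-spiking calls, 1 was kept without wild-type replicate 1 or 2, or null replicate 3 or 4. The number kept was 2 without null 1 and 5 without each other array. Of the 5 Purkinje calls, 1 was kept without wild-type 1 or null 3, and 2 without null 2. The number kept was 3, 5 and 4 without wild-type 2, wild-type 3 and null 1. The planned difference between the ages of the locus coeruleus was not run, because the value scales differ. Arrays of 3 against 3 and the GCRMA floor limit what could be called. For counts that moved, the cause was not tested unless stated.

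Counts moved by over 1.5 times as follows. Without the filter, fast-spiking gave 3, layer 5 gave 10, older locus coeruleus 40 and the difference between populations 220. With the strict filter, which means another level in the younger set, fast-spiking gave 8 and the difference 180. Quantile normalization gave 9 in fast-spiking and 49 in layer 5, and median centring 10 and 54. Without a variance trend, layer 5 gave 10 and Purkinje 8. Array weights gave 15 in fast-spiking, 104 in layer 5, 957 in older locus coeruleus, 9 in Purkinje, 1292 in younger locus coeruleus, 736 on average and 480 for the difference. The number of cells as a covariate gave 1 in older and 27 in younger locus coeruleus. The mean of all probe sets gave 15 in layer 5, 3 in Purkinje and 47 in younger locus coeruleus. Batch as a block gave 21 in fast-spiking, 14 in layer 5 and 286 on average. One fit over all 32 arrays, which mixes the scales, gave 72, 108, 368, 79 and 30 in fast-spiking, layer 5, older locus coeruleus, Purkinje and younger locus coeruleus. A plain test per gene gave 1, 0, 0, 0 and 5 in that order (400, 845, 965, 439 and 988 at an unadjusted p under 0.05). Without the pooled arrays, fast-spiking gave 0 (189 at an unadjusted p under 0.05), with 2 to 3 arrays per group.

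With replicate number as a block, fast-spiking gave 2, layer 5 gave 60, older locus coeruleus 22 and younger locus coeruleus 24. The numbers did not pair arrays in fast-spiking (own number best for 1 of 4 null arrays, r = -0.261 to 0.523), layer 5 (2 of 3) or the younger locus coeruleus (1 of 3). Seen from the wild-type arrays the counts were 1, 1 and 1. In the older locus coeruleus own number was best for 2 of 3 null and 3 of 3 wild-type arrays (r = 0.0636 to 0.216). Pairing stays open there, and with the block 18 of its 62 calls were kept. The block left Purkinje, the average and the difference within 1.5 times.

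Leaving out each array gave 1 to 10 genes in fast-spiking, 0 to 26 in layer 5, 1 to 207 in older locus coeruleus, 1 to 5 in Purkinje, 0 to 283 in younger locus coeruleus, 133 to 267 on average and 67 to 113 for the difference. The 0 counts had 732 and 785 genes at an unadjusted p under 0.05. The highest counts of both locus coeruleus sets came without null replicate 1. Markers ranged from 10 to 13 in fast-spiking, 7 to 9 in layer 5, 4 to 11 in locus coeruleus and 10 to 11 in Purkinje, and without the filter layer 5 gave 14.

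The long gene difference over the 4 populations was 0.0715 to 0.147 under all alternatives, each with a permutation p under 0.05. In older locus coeruleus it was 0.113 at 50 kb, 0.260 at 200 kb and 0.120 without the filter, and in fast-spiking 0.0806 with the mean of all probe sets (exact p = 0.0571) and 0.108 with the median (exact p = 0.114). In Purkinje it was 0.0529 with the mean of all probe sets (exact p = 0.3), 0.0575 without the filter, 0.072 at 50 kb (exact p = 0.3) and 0.09 with the median (exact p = 0.2). In layer 5 it was 0.000292 at 50 kb, 0.0552 at 200 kb, 0.0486 without the filter, 0.0146 with the mean of all probe sets and 0.0133 with the median. Leaving out each array gave 0.0997 to 0.116 over the 4 populations, 0.113 to 0.158 in fast-spiking, 0.00158 to 0.0442 in layer 5, 0.156 to 0.209 in older locus coeruleus, 0.0649 to 0.120 in Purkinje and 0.0942 to 0.147 in younger locus coeruleus.

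With an estimated correlation, 0 lists passed in each of the 6 comparisons (unadjusted p under 0.05 in 1, 0, 0, 1, 2 and 2 lists). With fry, 0 passed in fast-spiking, layer 5, Purkinje and younger locus coeruleus (unadjusted p under 0.05 in 1, 1, 1 and 3 lists), 1 in older locus coeruleus and 2 on average. The 1 was the list of fast-spiking interneuron markers, which camera did not call, so neither camera list was kept there, while the 2 on average were both camera lists. Without the filter 5 passed in older locus coeruleus and 1 in Purkinje. Leaving out each array gave 3 to 5 lists in fast-spiking, 1 to 5 in layer 5, 2 to 5 in older locus coeruleus, 1 to 4 in Purkinje, 3 to 5 in younger locus coeruleus and 6 to 8 on average.

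Only Irak1, which was never called, changed sign. In layer 5 it was -0.0341 after quantile normalization, -0.0593 after median centring, -0.133 with the number of cells, -0.0216 with the mean of all probe sets, and -0.0055, -0.077, -0.0535 and -0.118 without wild-type 1, wild-type 2, null 1 and null 3. In fast-spiking it was 0.0703 without null 4. In Purkinje it was 0.101 with array weights, 0.0127 with the number of cells, and 0.394, 0.02 and 0.0455 without wild-type 2, null 1 and null 3. On average it was 0.0553 with array weights and 0.0397 without Purkinje wild-type 2. Leaving out each array gave Irak1 values of -0.09 to 0.0703 in fast-spiking, -0.118 to 0.286 in layer 5, -0.36 to 0.394 in Purkinje and -0.149 to 0.0397 on average.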

Other observations

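The scores of lists per array were chosen after it was seen that no list held with an estimated correlation. Each score was the mean of a list minus the mean of the other kept genes, compared between null and wild-type arrays with labels permuted within the 4 older-age populations, for 21 lists. Glucocorticoid-responsive genes scored higher in null arrays by 0.164 (permutation p = 0.00762, adjusted p = 0.0361), with differences of 0.0401 in fast-spiking, 0.0979 in layer 5, 0.211 in locus coeruleus and 0.305 in Purkinje arrays. The list member Zbtb16, chosen after its values were seen, had a mean of 3.60 in wild-type and 6.54 in null Purkinje arrays. This 1 gene may account for much of the Purkinje difference, and the score without it was not computed. In the younger locus coeruleus the score difference was 0.0564 (exact p = 0.8). The planned camera test of this list passed in no comparison; on average its adjusted p was 0.140, with 7 of 12 members positive and 1 called. Neuropeptides and growth factors scored lower by -0.424, genes of the inhibitory synapse by -0.163, cholesterol genes by -0.152 and synaptic vesicle genes by -0.102 (adjusted p = 0.0361 each). Not every population went this way: the inhibitory synapse list had 0.00974 in fast-spiking and the cholesterol list 0.0124 in Purkinje arrays. In the younger locus coeruleus the 4 differences were -0.0398, -0.208, -0.0787 and 0.0491 in the same order. Long neuronal genes of the textbook list scored higher by 0.196 (adjusted p = 0.00458), while layer 5 alone had -0.0255 and the younger locus coeruleus 0.1704.

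With labels permuted within amplification batch, also chosen after the results were seen, these 6 lists still passed. So did adhesion (adjusted p = 0.0462), axon guidance (0.0262), catecholamine (0.0417) and sodium, calcium and HCN channel genes (0.0417).

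Other groups did not pass on this score with labels permuted within populations. Of them, 3 had passed camera on the average effect: adhesion genes outside the cadherins, with 0.124 (adjusted p = 0.0588), ribosomal genes, with 0.0721 (adjusted p = 0.147), and imprinted genes, with 0.0617 (adjusted p = 0.116). Immediate early genes, which respond to neuronal activity, had a difference of 0.294 (adjusted p = 0.157), with 0.711 in the older locus coeruleus and -0.136 in the younger. Genes of catecholamine synthesis and transport, the transmitter pathway of the locus coeruleus, had -0.138 (adjusted p = 0.116), axon guidance genes 0.112 (adjusted p = 0.0844) and sodium, calcium and HCN channels -0.128 (adjusted p = 0.0844). The other lists that did not pass were potassium channels, with 0.0777 (adjusted p = 0.147), X-linked neighbours of Mecp2, with -0.0433 (adjusted p = 0.423), and cadherins, with 0.0394 (adjusted p = 0.481). Heat shock genes had 0.0169 (adjusted p = 0.843) and genes of the excitatory synapse -0.00531 (adjusted p = 0.898). Genes named in earlier work as Mecp2 targets had -0.0495 (adjusted p = 0.651), genes of oxidative phosphorylation 0.00611 (adjusted p = 0.843) and chromatin and methylation regulators -0.0151 (adjusted p = 0.785). Cerebellar granule cell markers averaged 3.19 ± 0.12 in wild-type and 3.85 ± 0.13 in null layer 5 arrays (n = 3 each), a list that holds Chn2.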
